A study of Mus musculus with 12 samples.

How the data were processed

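Total RNA was taken from mouse astrocytes that had been derived from neural stem cells of the line labelled Rosa25/OG2. Per the labels' protocols, the cells were differentiated for 4 days in medium with 10% fetal calf serum, replated and matured for 14 days, then activated and treated for 4 h. Biotin-labelled RNA was made from 400 ng of input by in vitro transcription for 12 h and hybridised to Illumina bead arrays with 1 colour. Each label names 1 group, so the 12 groups hold 1 array each: a non-activated control, an activated control and 10 compounds on activated cells. The labels do not say how many cultures were pooled, and doses and structures of the compounds are not in them.

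The authors deposited a table with the mean bead intensity of each probe on each array, without normalisation per the file header, and a detection p-value per probe and array, also deposited by the authors, that sets the probe against the negative controls of its array. GenomeStudio 2010.3 is named in the submitters' processing notes, and whether background was subtracted is not given in the sources used here. The intensities ranged from medians of 117 (E4) to 127 (E14). A second deposited table holds the authors' processed intensities on a linear scale. In it 45.1% to 45.2% of the probes of each array stood at a floor of 10, and the array medians were 14.9 to 15.0. All 12 of its columns followed the column of the same sample in the first table best. Its scale was linear and its direction the same; the method of normalisation is not given in the sources used here. No array was given a genome build, so no coordinates are used.

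The intensities were background-corrected, quantile-normalised and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3, with background estimated from the detection p-values and an offset of 16. Of 25697 probes, 23978 had 1 gene symbol in the platform annotation, none had several, and 1719 were not listed there and stay unnamed; 668 of the unlisted probes were detected on at least 1 array. Symbols were looked up by gene ID in the RefSeq annotation table of mouse assembly GRCm38.p6 for 23962 probes, and 0 changed. A gene was represented by its brightest probe over all arrays, and 4777 of 16593 genes had more than 1 probe. The other detected probes of called genes went the same way in 149 of 157 cases for activation, 86 of 99 for E4 and 624 of 638 for E29. Counts and lists were computed in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

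A gene was measured in a comparison if its detection p-value was under 0.01 on at least 1 of the arrays compared. On an array that did not detect it, its value was raised to the lowest detected value of that array if it lay below, so that the change is a bound and is written as at least N-fold. A gene was called higher or lower at 2-fold. With 1 array per group, no test between groups, standard error or p-value was computed, and signal over background and the number of arrays limit the precision. The floor of an array lay between 5.37 (non-activated control) and 5.99 (E29) log2 units, so larger decreases of dim genes could not be seen.

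Before the data were examined, 26 gene lists with 434 genes were fixed, of which 388 had a named probe. They cover inflammatory cytokines and chemokines, NF-kB, interferon-gamma and type I interferon genes, effector enzymes, 3 lists of reactive astrocyte genes, stress, metabolic, nuclear receptor, p53, immediate early and cell cycle genes, growth factors, markers of astrocytes, neural stem cells and other brain cell types, and reference genes. A list was summarised by its median over measured members, if at least 5 were measured, and by the percentile of that median among 10000 random lists matched on mean expression in 20 bins, as a description of these arrays. Over all comparisons 213 medians were computed, and 89 lay outside the 95% range of their random lists. Members of a list move together for many reasons, and the lists overlap.

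The genes named were fixed by rule before the data were examined. For activation they were the 12 with the largest increase and the 12 with the largest decrease that lay on the same side in at least 8 of the 10 compound arrays. For each compound they were up to 5 per direction that were also 2-fold changed the same way against the median of the other 10 activated arrays. List members with the largest changes could be named as examples, and Nos2, Il6, Tnf, Il1b, Ccl2, Cxcl10, Hmox1, Nqo1 and Gfap were looked up in every comparison. Genes whose symbols start with LOC, Gm or ENSMUS or end in Rik were counted and not named. Activation-induced genes for a compound were those whose median over the other 9 compound arrays was at least 2-fold above the non-activated control, so that neither array compared chose them. Against the other 10 activated arrays this safeguard is lost, because 9 of those arrays chose the genes.

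All compounds share the activated control array, and every count was repeated against the median of the other 10 activated arrays. Further alternatives fixed in advance were no background correction, an offset of 50, scaling to a common median in place of quantile normalisation, the authors' processed values, a detection p-value of 0.05, no detection filter or bound, the mean of all probes of a gene, the median of all 11 activated arrays for the activation comparison, and induced genes chosen on the activated control. Normalisation without the E29 array and scaling to reference genes were added after seeing the data. The procedure was tested on simulated arrays for E4 against the activated control with 9707 measured genes. It called 100% of genes with a simulated log2 change of -2.5, 97.5% at -1.5, 100% at 1.5 and 94.3% at 2.5, and it called 7 unchanged genes. The changes were placed on bright probes only, with a log2 noise standard deviation of 0.15, and no other array was altered. The real E4 comparison had 7494 measured genes. These rates therefore do not describe dim genes or shifts of many genes at once.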

Results

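Gene expression was measured on 12 Illumina bead arrays in mouse astrocytes derived from neural stem cells, to find how 10 small-molecule hit compounds act on activated astrocytes. The non-activated control received no stimulus. The activated control received 1 µg/ml of lipopolysaccharide (LPS), a bacterial cell wall component sensed by Toll-like receptor signalling, together with 10 ng/ml of interferon-gamma, the type II interferon. The other 10 groups received the same stimuli followed by 1 compound each for 4 h. The compounds are known here only by the codes E4, E5, E14, E18, E19, E20, E21, E23, E29 and E33, and their doses are not in the labels. Each group is 1 array, so there are no replicates: every difference below is between single arrays, with no measured error and no p-value. A gene counts as higher or lower where it differed at least 2-fold. For scale, the smallest standard deviation over genes of the difference between 2 arrays was 0.20 log2 units, for E5 and the activated control, with 7 of 7395 measured genes 2-fold different. The fewest genes 2-fold different between 2 arrays were 3, for E20 and for E23 against the activated control.

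Each array carried 25697 probes. Between 9106 probes (E29) and 10719 probes (non-activated control) were detected above background, and the other 10 arrays lay between 10093 and 10609. Of 16593 named genes, 8128 were detected on at least 1 array and 5914 on all 12. Gfap, the intermediate filament protein of astrocytes, was detected on all 12 arrays at log2 intensities from 12.37 (activated control) to 12.87 (E33). None of the 14 microglia markers with a probe was detected on either control array.

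The first comparison asks what LPS with interferon-gamma changed in these astrocytes. Chemokines and interferon-gamma response genes had the largest increases. Cxcl10, a chemokine that attracts T cells, was 77.1-fold higher in the activated control than in the non-activated control, and Cd274, which encodes the checkpoint ligand PD-L1, was 65.8-fold higher. The fold of Cxcl10 is approximate, since the gene stood near the top of the intensity range, where normalisation sets values by rank: its log2 change was 6.27, 6.03 with scaling to a common median and 5.79 without background correction. The monocyte-attracting chemokines Ccl2 and Ccl7 were 54.1-fold and 37.6-fold higher. Cxcl9 was not detected without activation and was at least 45.4-fold higher with it. In all, 243 genes were higher and 162 were lower among 7659 measured genes. Genes were higher in 60.0% of these calls, against 51.1% when the arrays were scaled to a common median (229 higher, 219 lower), 51.3% with the median of all 11 activated arrays (196 higher, 186 lower) 47.7% with reference gene scaling (221 higher, 242 lower) and 72.5% without background correction (132 higher, 50 lower).

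The interferon-gamma and antigen presentation genes moved together: 19 of 22 measured members were higher, none was lower, and their median log2 change was 2.73, above the 95% range of random gene lists of matched expression (-0.19 to 0.09). Irf1, a transcription factor of the interferon response, was 8.12-fold higher, and the immunity-related GTPase Igtp was 40.7-fold higher. Both stood near the top of the intensity range in the activated control, so their folds are approximate, as for Cxcl10. The peptide transporter Tap1 and the immunoproteasome subunit Psmb9 were 10.1-fold and 10.3-fold higher. Further genes with large increases were the GTPases Gbp10 (32.5-fold) and Gbp2b (21.3-fold), Ifi47 (at least 70.5-fold), Parp14 (23.5-fold), the transcription factor Irf8 (at least 20.9-fold) and the matricellular protein gene Ccn1 (15.1-fold).

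Of 17 measured type I interferon-stimulated genes, 10 were higher, with a median log2 change of 1.19. Examples are the ubiquitin-like modifier Isg15 (10.3-fold), Oasl2 (9.10-fold) and the antiviral gene Rsad2 (7.41-fold). Of 11 measured NF-kB pathway and feedback genes, 10 were higher (median 1.42), among them Tnfaip3, a negative regulator of NF-kB, at 7.25-fold, Nfkbiz at 4.08-fold and the adhesion molecule Vcam1 at 3.30-fold. Of 8 measured inflammatory cytokines and chemokines, 5 were higher (median 2.20); beside Ccl2 and Ccl7 these were Ccl5 (8.13-fold), Cxcl1 (at least 10.3-fold) and Il6 (at least 2.61-fold). Il6 was detected on 5 of the 12 arrays, Nos2 only on the E21 array, Il1b only on the E19 array and Tnf on none. Nos2 stood at 5.46 log2 units in the activated control, 5.45 with E21 and 4.75 without activation. The lowest detected values of those arrays were 5.52, 5.41 and 5.37, so detection with E21 alone is no rise over the activated control. Of 12 measured immediate early genes, 7 were higher (median 1.30), with Egr2 at 7.29-fold and Crem at 4.77-fold.

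Lists of astrocyte reactivity differed in size of change. Of 7 measured genes of the A1 list, which is named for the state induced by neuroinflammation, 5 were higher (median 1.15): Gbp2, Iigp1, Serping1, H2-T23 and H2-D1. Gbp2, Iigp1 and H2-D1 also stand on the interferon-gamma list. Of 8 measured A2 genes 1 was higher (median 0.63), and of 10 pan-reactive genes 1, Cxcl10, was higher (median 0.35). Cholesterol synthesis genes had a median of 0.78, and 3 of 14 were higher, namely Idi1 (2.99-fold), Insig1 (2.47-fold) and Cyp51 (2.29-fold). Glucocorticoid-responsive genes had a median of 0.38 with 3 of 11 higher, including the phosphatase gene Dusp1 (3.60-fold), and 1 lower, Ddit4 (3.12-fold). p53 target genes lay below the random range with a median of -0.35, but went both ways: Plk2 and Fas were 5.40-fold and 2.19-fold higher, and Sesn1 and Bbc3 were 2.34-fold and 2.14-fold lower.

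Medians within the random range were found for astrocyte markers (-0.05), neural stem cell markers (0.19), cell cycle genes (0.12), reference genes (0.13), Nrf2 target genes (-0.12), heat shock genes (-0.14), unfolded protein and integrated stress response genes (-0.01) and hypoxia and glycolysis genes (-0.21). Within these lists the transcription factors Sox9 and Sox2 were 2.60-fold and 2.17-fold lower, Atf3 was 4.75-fold higher and hexokinase Hk2 was 2.94-fold higher. The genes with the largest decreases were Sybu (5.91-fold lower), the clock output gene Dbp (4.59-fold), the Wnt receptor gene Fzd10 (4.55-fold), Ddit4l (4.31-fold), Lrrc75b (4.23-fold), Tprkb (4.03-fold), Vps37b and Stard8 (both 4.02-fold), Adgra1 (3.97-fold), Hr (3.85-fold), Aatk (3.83-fold) and Sox8 (3.68-fold).

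**Figure D1:**
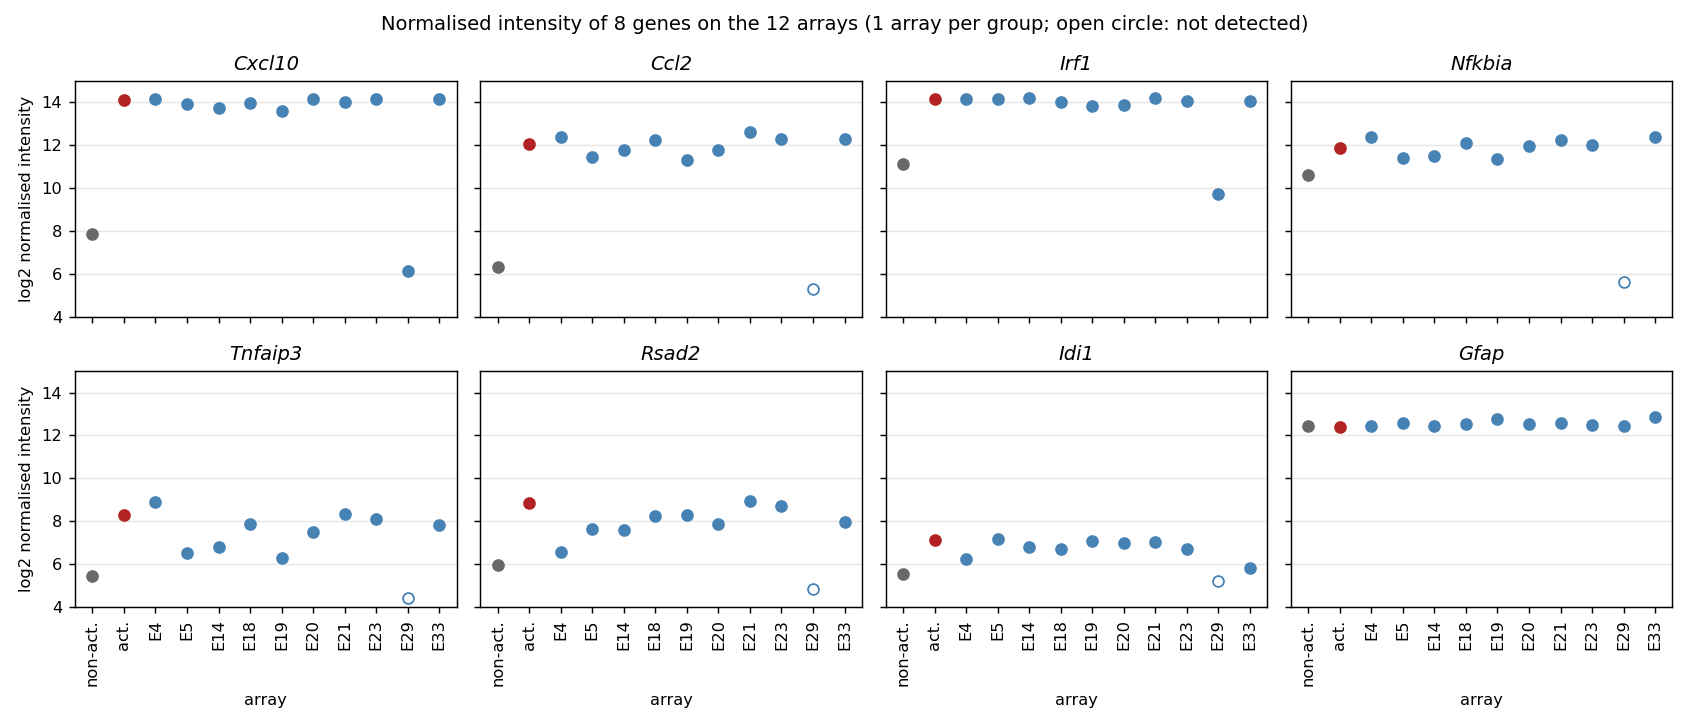
Log2 normalised intensity (vertical axis) of 8 genes on the 12 arrays (horizontal axis; non-act. and act. are the 2 controls), 1 point per array, open where the gene was not detected. Cxcl10 lies at 7.86 without activation, 14.13 with activation and 6.12 with E29, while Gfap lies between 12.37 and 12.87 on all 12 arrays.

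The next comparisons ask what each compound changed in activated astrocytes, each set against the same activated control array. The compounds differed widely in reach. E29 changed 1842 of 7472 measured genes (760 higher, 1082 lower), E4 changed 253 (37 higher, 216 lower) and E33 changed 73 (15 higher, 58 lower). E19 (4 higher, 26 lower), E18 (3 higher, 19 lower) and E14 (2 higher, 19 lower) changed 30, 22 and 21 genes. E21 (7 higher, 1 lower), E5 (7 lower), E20 (3 lower) and E23 (3 higher) changed fewer than 10 each. Of the 1082 lower genes with E29, 347 were not detected on that array, so that their changes are bounds. The E29 array detected the fewest probes (9106), and poorer RNA on it could not be excluded. Because all compounds share 1 activated control array, part of each count is that array's own deviation. Against the median of the other 10 activated arrays the counts were 615 higher and 999 lower for E29, and in all 156 for E4, 40 for E33, 8 for E19, 6 for E21, 4 for E18 and E14, 2 for E5 and E23 and 1 for E20. Genes changed the same way against both references numbered 539 higher and 973 lower for E29, 28 and 109 for E4, and 9 and 22 for E33.

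E29 lowered most of the activation-induced genes. Cxcl10 was 257-fold lower than in the activated control (log2 change -8.01, -8.33 with median scaling and -6.77 without background correction), Cd274 was 125-fold lower, Ccl7 was at least 192-fold lower and Ccl2 was at least 68.0-fold lower. Of the 243 genes that activation raised, 195 were lower with E29 and none was higher, and 69 lay at least 2-fold below the non-activated control. In a set of 202 induced genes chosen without either array compared, the median log2 change was -2.22, where random lists lay between 0.04 and 0.31. E29 was also the single compound array nearer to the non-activated control (standard deviation of the difference 0.90) than to the activated control (1.03). It lay almost as near to E4 (0.91) and E33 (0.92). By genes 2-fold different, E4 (1126) and E33 (1423) were nearer to E29 than the non-activated control was (1560).

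The interferon-gamma and antigen presentation genes had a median of -2.54 with E29, and 16 of 22 were lower, among them Irf1 (21.5-fold), Igtp (55.4-fold) and Irgm2 (43.5-fold). Of 12 NF-kB pathway and feedback genes 10 were lower (median -1.86). Nfkbia, which encodes the NF-kB inhibitor IkB-alpha and was 2.38-fold higher on activation, was not detected with E29 and was at least 59.6-fold lower. Immediate early genes had a median of -2.55, with 9 of 13 lower, including Ier3 (17.1-fold), Junb (16.5-fold) and Jun (at least 13.1-fold), and 1 higher, Fosb (at least 2.21-fold). Of 8 inflammatory cytokines and chemokines 5 were lower (median -1.64), and of 17 type I interferon-stimulated genes 7 were lower, with Parp14 34.8-fold and Ifi47 at least 46.1-fold lower. The type I median was -0.58, -0.27 for the same genes against the other 10 activated arrays and -1.48 without raising undetected values to the array floor.

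The decreases with E29 reached beyond inflammatory genes. Cebpb, a transcription factor gene expressed on both control arrays, was 69.3-fold lower than with activation alone and lay 5.58 log2 units below the non-activated control. Rasl11a was at least 156-fold lower. Cholesterol synthesis genes had a median of -1.18 with 8 of 14 lower (Msmo1 6.23-fold, Cyp51 5.01-fold), p53 target genes -1.25 with 7 of 12 lower, glucocorticoid-responsive genes -0.81 with 5 of 11 lower and 1 higher (Sgk1 40.4-fold lower, Tsc22d3 2.18-fold higher), A2 genes -0.88 with 4 of 8 lower, pan-reactive genes -0.42 with 4 of 10 lower (0.03 with no detection filter or bound), and unfolded protein and integrated stress response genes -0.62 with 6 of 17 lower. Without raising undetected values to the array floor, the glucocorticoid-responsive median was -1.93 and the A2 median -2.08. Hmox1, which encodes the haem-degrading enzyme, was 4.78-fold lower, while the Nrf2 list as a whole had a median of 0.14 (5 of 17 lower, 1 higher). Heat shock genes had a median of 0.19, although the cochaperone gene Dnajb1 was 6.35-fold lower. The A1 list (-0.41), neural stem cell markers (-0.93), hypoxia and glycolysis genes (0.55), cell cycle genes (0.27) and reference genes (0.33) lay within the random range. Of 4350 genes that activation moved by under 0.3 log2 units, 392 were higher and 409 were lower with E29, which is 18.4% of them.

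Among the increases with E29 were Id4, an inhibitor of basic helix-loop-helix transcription factors (9.28-fold), Tmem86a (6.17-fold), Adamts16 (5.81-fold), the U6 small nuclear RNA gene Rnu6 (5.31-fold) and Tmie (5.08-fold). Astrocyte markers had a median of 0.47, above the random range, and 2 of 14 were higher, Aldh1l1 (2.16-fold) and Ndrg2 (2.03-fold). These increases depend on the scaling. The median change of all genes with E29 was 0.25 in the main setting, 0.00 with scaling to a common median and -0.33 with scaling to reference genes. Relative to that median, astrocyte markers stood at 0.21, 0.41 and 0.41 and activation-induced genes at -2.47, -2.90 and -2.99. The split of the calls moved with it, from 760 higher and 1082 lower (41.3% higher) to 158 and 1563 with median scaling (9.18%), 33 and 2041 with reference gene scaling, 353 and 918 with a larger offset (27.8%) and 106 and 705 without background correction (13.1%). Counted from the median of all genes, 279 genes were higher and 1372 lower.

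**Figure D2:**
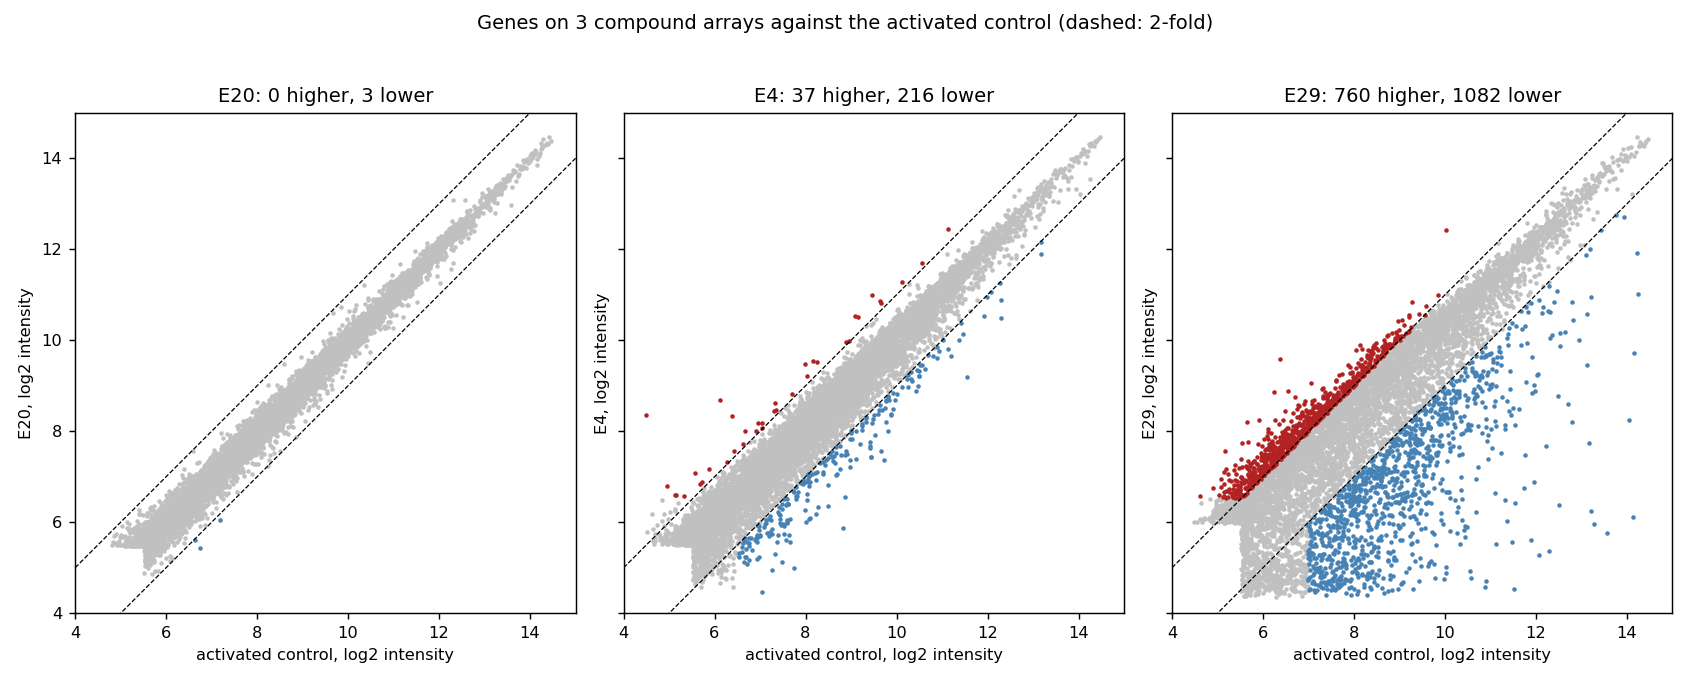
Log2 normalised intensity of measured genes in the activated control (horizontal axis) against E20, E4 and E29 (vertical axes), 1 point per gene, with values on arrays that did not detect a gene drawn as measured, so that gray points beyond the lines are genes whose bound is under 2-fold; red points are at least 2-fold higher, blue points at least 2-fold lower, and dashed lines mark 2-fold. E20 has 3 coloured points, E4 has 253 and E29 has 1842.

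E4 lowered interferon-stimulated genes. Of 17 type I interferon-stimulated genes 9 were lower and none was higher (median -1.03, random range -0.21 to 0.23). Against the other 10 activated arrays their median was -0.61, and 6 of the 17 were highest on the activated control among the 11 activated arrays. Parp14 was 5.06-fold lower, Rsad2 4.93-fold, Usp18, which removes Isg15 from proteins, 3.10-fold, Oasl2 2.86-fold and Isg15 2.69-fold. Of 22 interferon-gamma and antigen presentation genes 6 were lower (median -0.56; -0.41 for the same genes against the other 10 arrays, and -0.22 for all list members measured against those), with Gbp5 at 3.37-fold. Ccl2 changed by 0.30 log2 units, and none of 9 measured cytokines and chemokines passed 2-fold in either direction (median 0.22). For the same genes of this list the median against the other 10 activated arrays was 0.44. Cxcl10, which is not on that list, stood near the top of the intensity range in the activated control (14.13) and with E4, E20 and E23 (14.14 each). Normalisation sets values there by rank, so small differences in Cxcl10 were not read. The NF-kB list had a median of -0.20, within the random range, with Nfkb2 2.65-fold lower. For the same genes against the other 10 activated arrays the median turned to 0.11.

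Immediate early genes stood above the random range with E4 (median 0.59), and 4 of 15 were higher: Egr1 (2.56-fold), Fos (2.07-fold), Pde4b (2.05-fold) and Fosb (at least 2.10-fold). This list lay below the random range with 5 compounds, namely E5, E14, E19, E20 and E29. The MAP kinase phosphatase gene Dusp4 was 3.88-fold higher with E4. Cholesterol synthesis genes had a median of -0.55, all 14 lay below the control and 1, Lss, passed 2-fold (2.04-fold lower). Neural stem cell markers had a median of -0.49, with Notch1 3.12-fold and Sox2 2.12-fold lower. The A1 list (-0.42, 1 of 7 lower), the A2 list (-0.36, 1 of 8 lower) and p53 target genes (-0.30, 2 of 12 lower) lay below the random range, but against the other 10 activated arrays they stood at -0.25, -0.25 and -0.04, and with no detection filter or bound the A2 median turned to 0.05. Unfolded protein and integrated stress response genes lay above the random range (0.24, 1 of 17 higher, Chac1 at 2.11-fold) and stood at 0.16 against those arrays and at -0.15 with reference gene scaling, which is 0.17 above the median of all genes in that scaling. Against the other 10 arrays immediate early genes stood at 0.64, cholesterol synthesis genes at -0.56 and neural stem cell markers at -0.37. Osmr, a receptor subunit for oncostatin M, and Lcn2, both pan-reactive genes, were 3.44-fold and 3.49-fold lower, in a list whose median was -0.11.

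The genes changed most by E4 were Eid3 (at least 7.11-fold higher), the RNA-binding protein gene Rbm15 (5.96-fold), Dusp4, Csrnp1 (2.92-fold) and Dnal1 (2.86-fold), and on the lower side Zbtb7c (7.78-fold), the actin-regulating kinase gene Limk2 (5.13-fold), Parp14, Rsad2 and Runx1 (at least 4.78-fold). Rbm15 and Zbtb7c also changed with E18, by 2.34-fold upward and 3.10-fold downward, and E18 was the array nearest to E4 (90 genes apart). The share of higher calls among the E4 calls was 14.6% in the main setting, 4.43% with median scaling (19 higher, 410 lower), 26.3% against the other 10 activated arrays (41 higher, 115 lower), and 9 were higher and 693 lower with reference gene scaling. The median change of all genes was 0.04, -0.14 and -0.32 in the main, median and reference gene scalings. Relative to it, type I interferon-stimulated genes stood at -1.06, -1.12 and -1.12 and immediate early genes at 0.56, 0.47 and 0.47.

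E33 lowered genes of cholesterol synthesis, which had a median log2 change of -0.76 (random range -0.16 to 0.17). Of 14 genes, 13 lay below the control and 3 passed 2-fold, namely Idi1 (log2 change -1.32), Lss (-1.27) and Cyp51 (-1.10). The A2 list had a median of -0.62 with 1 of 8 lower (Sphk1, a sphingosine kinase, 2.97-fold), the glucocorticoid-responsive list -0.46 with none of 11 past 2-fold, and the A1 list -0.38 with none of 7. Against the other 10 activated arrays the medians were -0.73 for cholesterol synthesis, -0.52 for A2, -0.31 for glucocorticoid-responsive and -0.16 for A1 genes. Osgin1 was 5.34-fold lower, the neuropeptide precursor gene Vgf 5.22-fold, the activin-binding follistatin gene Fst 3.96-fold, AA467197 3.54-fold and Cxcl9 3.45-fold. On the higher side were Hsd3b2 (3.59-fold), the Polycomb gene Cbx8 (3.40-fold), the long noncoding RNA Xist (3.12-fold), Sybu (2.37-fold) and the cytolinker gene Dst (2.34-fold). With the mean of all probes Hsd3b2 and Dst stood at 0.36 each and Xist at 1.40. Of 8 cytokines and chemokines 2 were lower with E33, Ccl5 (2.35-fold) and Il6 (at least 2.53-fold), and Ccl2 changed by 0.21 log2 units. Il6, at 6.76 log2 units in the activated control, was also not detected with E5, E14, E19, E20 and E29. The list had a median of -0.41, below the random range, and -0.15 for the same genes against the other 10 arrays. The induced genes had a median of -0.36, and -0.20 against those arrays, 9 of which chose the genes.

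E5, E14 and E19 lowered Tnfaip3 and Cxcl1. Tnfaip3 was 3.38-fold lower with E5, 2.81-fold with E14 and 4.00-fold with E19, and the neutrophil-attracting chemokine Cxcl1 was 2.91-fold, 2.83-fold and 4.91-fold lower. Against the other 10 activated arrays Tnfaip3 stood at -1.33, -1.06 and -1.57 log2 units and Cxcl1 at -1.18, -1.14 and -1.93. Ccl5 was 3.19-fold lower with E14 and 3.99-fold lower with E19. The NF-kB list had medians of -0.48, -0.43 and -0.68 with E5, E14 and E19, and the cytokine and chemokine list had medians of -0.52, -0.41 and -0.66. For the same genes against the other 10 activated arrays the medians were smaller, at -0.21, -0.20 and -0.28 for NF-kB and -0.34, -0.29 and -0.32 for cytokines and chemokines. Against the activated control all 6 medians lay below the random range, while few members were 2-fold lower: 1 of 11, 1 of 11 and 2 of 11 NF-kB genes, and 3 of 8, 3 of 8 and 3 of 11 cytokines and chemokines. With E19, 1 further member, Ccl4, was higher. Other lists also lay below the random range with E5, E14 and E19. Type I interferon-stimulated genes had medians of -0.41, -0.63 and -0.53. Interferon-gamma and antigen presentation genes had medians of -0.10, -0.31 and -0.30, and immediate early genes of -0.33, -0.12 and -0.46. For the same genes against the other 10 activated arrays, interferon-gamma medians were 0.05, -0.13 and -0.13. Immediate early medians were -0.20, -0.05 and -0.29 there. The NF-kB list lay below the random range with 6 compounds and the cytokine and chemokine list with 7. Beside E5, E14, E19 and E29 these were E18 (-0.25 and -0.29), E33 (-0.30 and -0.41) and, for cytokines and chemokines, E20 (-0.37). For the same genes these 5 further medians lay between -0.15 and 0.06 against the other 10 activated arrays. With E19, Egr2 (2.63-fold) and Erdr1 (2.92-fold) were also lower. With E14, the small heat shock protein gene Hspb1 was 2.05-fold higher, in a heat shock list whose median was -0.05.

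E19 was also the array with Ccl4 and Gpnmb above the detection limit. Ccl4, a macrophage inflammatory protein, was at least 2.35-fold higher than in the activated control. Gpnmb, a transmembrane glycoprotein of phagocytes, was at least 3.83-fold higher by its brightest probe, but its 4 probes disagreed, and their mean changed by -0.23 log2 units. The scaffold protein gene Ahnak was 2.08-fold higher with E19. None of the 4 genes called higher with E19 stayed past 2-fold with the mean of all probes, where Ahnak stood at 0.59 and Ccl4 at 0.44 log2 units, or without background correction, where Ccl4 stood at 0.01.

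E18, E20, E21 and E23 changed few genes. With E18, Clec2d, a C-type lectin gene raised by activation, was 3.62-fold lower. With E20, the carboxypeptidase gene Cpd was 2.04-fold lower. With E21, Hsd3b2 (2.97-fold), the endocytic receptor gene Lrp1 (at least 2.71-fold), Dst (2.70-fold), Ahnak (2.57-fold) and Xist (2.26-fold) were higher. With the mean of all probes of a gene the 7 higher calls with E21 fell to 3, and Hsd3b2 stood at 0.36, Dst at 0.46, Ahnak at 0.77 and Xist at 1.01 log2 units. With E23, Ccno was 2.39-fold higher. Among the list medians above the random range with no member past 2-fold were those of A2 genes (0.28, 7 of 8 above 0) and neural stem cell markers (0.23, 4 of 6) with E21, and cholesterol synthesis genes with E20 (0.26, 13 of 14), E5 (0.26, 14 of 14) and E19 (0.18, 12 of 14). They stood at 0.33, 0.34, 0.36, 0.28 and 0.26 against the other 10 activated arrays. Induced-gene medians were -0.07 with E18, -0.17 with E20, 0.03 with E21 and -0.09 with E23, and against the other 10 activated arrays they were 0.13, -0.03, 0.20 and 0.07. The genes had been chosen on 9 of those 10 arrays. The splits of the calls moved with scaling. With median scaling they were 1 higher and 40 lower for E18, 6 and 2 for E21 and 1 and 2 for E23. With reference gene scaling they were 0 and 84, 6 and 3, and 1 and 3, and for E20 1 and 2. In the main setting the reference genes stood at 0.18 with E18, above the random range, and at 0.22 with E4, within it. Scaling on them therefore moves the other genes down on those arrays.

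Hmox1 stood at 0.69, 0.70, 0.93 and 0.77 log2 units above the activated control with E5, E14, E19 and E20, each short of 2-fold, and the Nrf2 list medians were 0.07, 0.04, 0.10 and 0.11. The activated control had a low Hmox1 value (12.31), below all compound arrays but E29 (10.05) and E33 (11.94). E18 (12.76) and E23 (12.86) also lay above it, so part of these rises may be the control array's own deviation. Nqo1 changed by at most 0.26 log2 units upward outside E29, where it was 0.68 higher. Gfap passed 2-fold in no comparison; its largest difference was 0.50 log2 units with E33. Type I interferon-stimulated genes had medians below the activated control with all 10 compounds, but 6 of the 17 genes were highest on that single control array among the 11 activated arrays. Against the other 10 activated arrays the medians of E20 (0.04), E21 (0.26), E23 (0.22) and E33 (0.22) lay above 0. Those of E5 (-0.02), E14 (-0.21), E18 (-0.16), E19 (-0.10) and E29 (-0.27) lay below it. Interferon-gamma and NF-kB medians also lay below the activated control with all 10 compounds. On that array 9 of 22 and 3 of 11 of their genes were highest. Cytokine and chemokine medians lay below it with 9 compounds, and 0 of 8 genes were highest on it. Medians of p53 target genes lay below the random range with 8 compounds. Against the other 10 activated arrays those medians lay between -0.06 and 0.04, E29 (-0.84) apart.

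**Figure D3:**
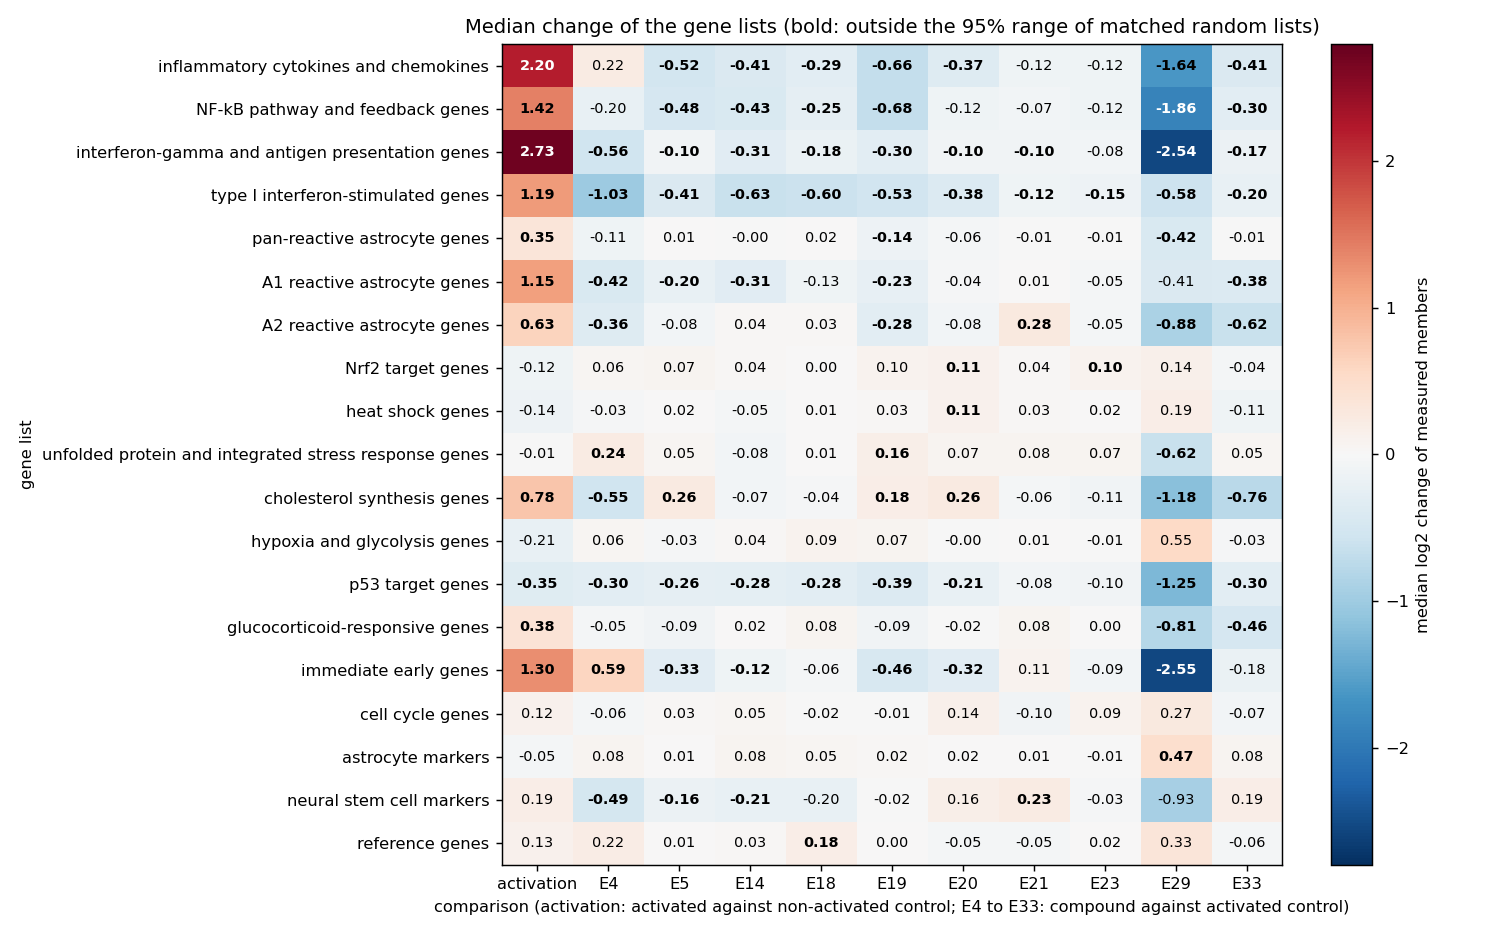
Median log2 change of the measured members of 19 gene lists (rows) in 11 comparisons (columns): the activated against the non-activated control, then each compound against the activated control. Bold values lie outside the 95% range of matched random lists; interferon-gamma genes go from 2.73 on activation to -2.54 with E29, and E4 has its lowest value, -1.03, in the type I interferon list.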

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

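Each count, induced-gene median, list median and named gene was recomputed with the alternatives that apply to it, and reference gene scaling and normalisation without the E29 array were chosen after seeing the data. With 1 array per group, a control array or a compound array that deviates cannot be told from an effect by leaving arrays out, and dim genes are limited by the signal over background. No paired analysis was possible because each group holds 1 array. No split of the arrays into groups was possible for the same reason. In each setting that changes the values, 9 compound arrays were nearer to the activated than to the non-activated control. Of the named genes' recomputed values, 476 differed little from the main ones, 206 moved and 1 changed sign; of the list medians, 1853, 215 and 24 did. Normalisation without the E29 array moved no count of changed genes of the other compounds by over 1.5 times. The values of counts and induced-gene medians that moved, and of all results that changed sign, follow, and the cause was not tested. Main induced-gene medians not given above were -0.15 (E4), -0.21 (E5), -0.17 (E14) and -0.28 (E19). Without background correction, counts of changed genes were 182 (activation), 79 (E4), 3 (E5), 7 (E14), 5 (E18), 6 (E19), 0 (E20), 4 (E21), 0 (E23), 811 (E29) and 21 (E33). The induced-gene medians were -0.27 (E4), -0.23 (E14), -0.13 (E18), -0.35 (E19), -0.22 (E20) and -0.29 (E33). Against the median of the other 10 activated arrays, counts of changed genes were 156 (E4), 2 (E5), 4 (E14), 4 (E18), 8 (E19), 1 (E20) and 40 (E33). The induced-gene medians were -0.030 (E4), -0.072 (E5), -0.046 (E14), 0.13 (E18), -0.11 (E19), -0.029 (E20), 0.20 (E21), 0.067 (E23), -2.06 (E29) and -0.20 (E33). For these medians the genes had been chosen on 9 of the 10 reference arrays. The list medians in this setting were taken over all list members measured against those arrays, so some differ from the values given above for the same genes. List medians that changed sign were 0.017 (E5), 0.13 (E20) and 0.15 (E21) for interferon-gamma and antigen presentation genes, 0.031 (E5) for A1 reactive astrocyte genes, 0.0021 (E5), 0.037 (E19) and 0.011 (E20) for p53 target genes, 0.12 (E18) for inflammatory cytokines and chemokines, 0.062 (E18) and 0.046 (E33) for NF-kB pathway and feedback genes and 0.040 (E20), 0.26 (E21), 0.22 (E23) and 0.22 (E33) for type I interferon-stimulated genes. With an offset of 50, counts of changed genes were 148 (E4), 11 (E14), 8 (E18), 19 (E19), 0 (E20), 5 (E21), 1 (E23) and 36 (E33). The induced-gene medians were -0.23 (E14) and -0.11 (E18). With scaling to a common median, counts of changed genes were 429 (E4), 41 (E18) and 5 (E20). The induced-gene medians were -0.36 (E4), -0.14 (E18), -0.39 (E19), -0.26 (E20), -0.21 (E23), -2.91 (E29) and -0.48 (E33). The list median that changed sign was -0.022 (E23) for Nrf2 target genes. With reference gene scaling, counts of changed genes were 702 (E4), 84 (E18) and 48 (E19). The induced-gene medians were -0.56 (E4), -0.27 (E5), -0.23 (E14), -0.26 (E18), -0.48 (E19), -0.067 (E21), -0.26 (E23), -3.32 (E29) and -0.44 (E33). List medians that changed sign were -0.15 (E4) and -0.014 (E19) for unfolded protein and integrated stress response genes, -0.071 (E18) for reference genes and -0.071 (E23) for Nrf2 target genes. Both scalings shift all genes, and relative to the median of all genes the list medians that changed sign with them kept it (0.11 to 0.17). With induced genes chosen on the activated control, induced-gene medians were -0.35 (E4), -0.25 (E5), -0.24 (E14), -0.16 (E18), -0.017 (E21), -0.13 (E23), -2.06 (E29) and -0.44 (E33). With no detection filter or bound, the induced-gene median was -2.53 (E29). List medians that changed sign were 0.052 (E4) for A2 reactive astrocyte genes, 0.019 (E20) for inflammatory cytokines and chemokines and 0.034 (E29) for pan-reactive astrocyte genes. With the authors' processed values, counts of changed genes were 35 (E18), 6 (E20) and 113 (E33). The induced-gene medians were -0.027 (E18) and -2.04 (E29). With the mean of all probes of a gene, the count of changed genes was 3 (E21). List medians that changed sign were 0.037 (E19) for pan-reactive astrocyte genes and -0.052 (E23) for Nrf2 target genes. The Gpnmb change with E19 was -0.23. With a detection p-value of 0.05, the induced-gene median was -2.39 (E29).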

Other observations

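Some of the fixed lists had fewer than 5 measured members in most or all comparisons, where no median was taken. The medians that were taken, for effector enzymes and acute-phase genes with E4 (-0.17) and E21 (-0.07) and for neuron markers with E14 (-0.05) and E21 (-0.0034), lay within the random range. Among effector enzymes and acute-phase genes, Gch1, which makes the tetrahydrobiopterin needed for nitric oxide synthesis, was 2.41-fold higher on activation and 11.4-fold lower with E29 than in the activated control. Lcn2 was 3.49-fold lower with E4 than in the activated control, 3.18-fold with E29, 2.46-fold with E18, 2.21-fold with E19 and 2.07-fold with E14, but that array had the highest Lcn2 of the 11 activated arrays. Against the other 10 activated arrays Lcn2 passed 2-fold with E4 alone (-1.11 log2 units). Among growth factors, the neurotrophin gene Bdnf was 10.6-fold lower and Hbegf 5.12-fold lower with E29, while Tgfb2 was 2.28-fold higher; Hbegf was 2.18-fold higher on activation. Of 4 measured neuron markers, Syt1 was 2.86-fold higher with E29, and of the 2 measured oligodendrocyte lineage markers Cnp was 2.47-fold higher, against a median of all genes of 0.25 log2 units on that array. Acta2, the single measured endothelial and mesenchymal marker, was 3.90-fold lower with E29. The 3 measured aryl hydrocarbon receptor targets changed by -0.19 (Cyp1b1), -0.06 (Aldh3a1) and 0.14 (Nqo1) log2 units on activation.

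Xist and Dst were higher with both E21 and E33, as was Hsd3b2, whose symbol has 6 probes on the array. With the mean of all probes of a gene Xist alone of these stayed past 2-fold, at 1.01 log2 units with E21 and 1.40 with E33. Xist stood at 8.35 log2 units in the non-activated control, 8.96 in the activated control, 10.13 with E21 and 10.60 with E33. Numbers of genes detected on a single array were 140 for the non-activated control, 46 for E4, 45 for E21, 31 for E33 and 28 for E29, and 23 or fewer for the other arrays.

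All tests below were chosen after the results were seen. With E29, 195 of the 243 activation-induced genes were lower, the array detected 9106 probes where the other 11 detected 10093 to 10719, and 998 genes lay at least 2-fold below the non-activated control and 562 at least 2-fold above it. Selective reversal of activation as the whole cause is argued against by the 18.4% of genes not responding to activation that differed 2-fold with E29, where the highest share among the other compounds was 1.73%. A weaker signal of all genes on that array is argued against by the 8 reference genes. Their raw median signal on it was 9.77 log2 units, above the range of 9.24 to 9.51 on the other 11 arrays. The raw 75th percentile of the E29 array was the lowest, at 203, with E4 next at 215. A few abundant genes therefore cannot exclude poorer RNA on that array. Another explanation that stays open is a loss of short-lived transcripts, as a block of RNA synthesis would give. In the main setting, 29 measured transcripts from a list of 38 known to turn over fast had a median of -0.90 against the non-activated control. That lies between the bounds set for and against it (-1 and -0.5), and at percentile 0 of matched random lists. With the other compounds the median lay between 0.13 (E33) and 0.39 (E21). The other scalings, which shift all genes with E29, were not applied to this test. The test decides nothing, because the list was drawn up after the results were seen and shares Klf6, Plk2, Per1 and other genes with lists already found lower with E29. An effect of E29 on signalling that induced and short-lived transcripts both need was not tested.

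With E19, 8 genes were detected on that array alone, and among them, chosen after their values were seen, were Il1b, Ccl3, Ccl4, Gpnmb, Laptm5 and Lpl, which macrophages express. Cells of the microglia or macrophage lineage in that culture may be the source, but 14.3% of the 14 microglia markers with a probe (2 of them, Laptm5 and Fcer1g) were highest on the E19 array, and 1 of the 14 was detected on any array. A bound of 20% had been set, at or below which the markers would speak against such cells; it was set aside after the value was seen, because markers below the detection limit could not show a small share of cells. Tyrobp and C1qa, abundant in microglia, stood at 4.65 and 4.55 log2 units with E19 and at medians of 4.63 and 4.57 on the other arrays, all below detection. Induction of these genes by E19 in astrocytes and a few cells of another type cannot be told apart with 1 array.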
